A study of Mus musculus with 6 samples.

How the data were processed

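CpG methylation was measured by whole-genome bisulfite sequencing in mouse embryonic stem cells that lacked DNMT1, DNMT3A and DNMT3B. The cells expressed DNMT3A2, DNMT3B1, or DNMT3B1 with SETD2 knocked out as well. Bisulfite treatment converts unmethylated cytosines, so a read that keeps a C at a CpG counts as methylated. Per the labels' protocols, cells were grown on feeder cells or gelatine, DNA was sonicated and size-selected, and methylated T7 and unmethylated lambda phage DNA were spiked in as conversion controls. The 6 samples in the labels were 2 sequencing runs for each of 3 lines. Groups were taken from the sample titles. The titles named the sequencing instrument for the DNMT3A2 and DNMT3B1 runs, and single or paired-end for the knockout runs. The labels named no separate cultures, so the runs were treated as technical and each line as 1 library.

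The deposited series table gave, per the file headers, the coverage of each CpG site in total reads for the DNMT3A2 and the DNMT3B1 line. It also gave, per the file headers, the count of methylated reads of each line, with both strands of a CpG on 1 line. The headers name the cell line and not the run, so both runs were taken as pooled. The deposited values of the SETD2 knockout line gave coverage, the count of methylated reads and their fraction at each site, and that fraction equalled methylated reads over coverage at every site listed. The 2 knockout files were identical and were used once. The knockout values held only sites with at least 10 reads (44.7% of the 20782144 sites of the series table). The genome build was mm9, per the submitters' processing notes. The aligner, the methylation caller and any treatment of duplicate or multiply mapping reads are not given in the sources used here. Copies of repeated DNA that map to 1 position, and amplified duplicates counted as separate reads, would both enter these counts, so binomial intervals cover counting error only.

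Before the data were examined, the following choices were fixed. A site entered a comparison with at least 5 reads in each line compared and at most 5 times the median coverage of each line. That maximum was 45 reads for DNMT3A2, 40 for DNMT3B1 and 80 for the SETD2 knockout, whose median was that of listed sites. It removed 7405, 14956 and 4736 sites, which held 14.0%, 13.3% and 15.6% of reads. Levels are methylated reads over all reads, pooled over sites, with exact (Clopper-Pearson) 95% binomial intervals. CpG density is the number of CpG sites of the series table within 500 bp on each side of a site, itself included, in 6 bins. Tiles of 10 kb with at least 20 sites were compared by the log2 ratio of their levels minus the log2 ratio of the genome-wide levels on the same sites, called the relative log2 ratio. Its 95% interval came from a ratio estimator over 500 bp clusters of CpGs, since neighbouring CpGs share reads. A tile was counted as higher or lower at a relative ratio of at least 2-fold with an interval excluding 0. A tile with no methylated read was set to a floor of 3 reads, so that it ranks as less extreme than a tile with 1 methylated read. This floor was the exception and was not part of the plan. With the background subtracted, every level below 3 reads was raised to it. The text names the 5 highest and the 5 lowest tiles of each comparison among those with at least 500 reads in each line and an interval excluding 0.

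The dependence of the DNMT3B1 preference on SETD2 was measured in tiles with at least 10 sites in odd-numbered and in even-numbered clusters. Tiles were ranked by DNMT3B1 over DNMT3A2 in odd-numbered clusters, and median ratios per decile were taken from even-numbered clusters, with levels floored at 0.5 reads. Standard errors came from leaving out 1 chromosome at a time. Correlations between lines were estimated from the covariances between odd-numbered and even-numbered clusters, which removes counting error, in tiles with at least 60 reads of each line in each set of clusters. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

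The tile test was tested on simulated data with the real coverage, the estimated variation between clusters and 200 tiles changed in each direction. The changed tiles were drawn only from those above a minimum methylation level relative to the mean, so recovery in weakly methylated tiles was not simulated. For DNMT3B1 over DNMT3A2 in 160890 tiles, 96% of tiles raised 4-fold and 67.5% of those lowered 4-fold were called, and 79% and 64% at 3-fold. For the SETD2 knockout over DNMT3B1 in 120431 tiles, 95% and 78% were called at 4-fold, and 82% and 67% at 3-fold. The relative variance between clusters was estimated as 0.213 for DNMT3A2 and 0.556 for DNMT3B1 in the first comparison, and as 0.550 for DNMT3B1 and 0.158 for the SETD2 knockout in the second. A value of 1 was also used, and the number of unchanged tiles called is given with each comparison for both. In a separate simulation the correlation estimate came within 0.007 of the known value in 96367 tiles. That simulation gave each tile 1 level per line, without variation between clusters and without reads shared across cluster borders. It therefore checked the removal of counting error only.

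Alternatives were a coverage minimum of 1 or 10 reads, no coverage maximum, the mean of the sites' own levels, tiles of 5 or 50 kb, percentile ranks, and subtraction of the level of the densest CpG bin as background. For the dependence on SETD2 they were also the use of all clusters, and autosomes only. The sites of each line alone, autosomes only for the genome-wide level, sites with 10 to 19 CpGs per kb, clusters of 2 kb, which have fewer borders for reads to span, and the settings of the tile correlations were added after seeing the data. No correction for unconverted cytosines was made, because neither spike-in nor mitochondrial sites were among the values analysed here. Gene bodies, gene lists fixed beforehand and profiles along genes were left out, because the gene table used here is of assembly GRCm38.p6 and positions were not converted between builds. Methylation by flanking base and by strand was left out for lack of a genome sequence and of values per strand. The methylation data do not check the labels of the knocked-out or reintroduced genes.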

Results

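Whole-genome bisulfite sequencing measured CpG methylation in 3 lines of mouse embryonic stem cells that lacked the endogenous DNA methyltransferases DNMT1, DNMT3A and DNMT3B and carried a single reintroduced enzyme. DNMT1 copies methylation onto new DNA strands, and DNMT3A and DNMT3B set it de novo. The first line expressed DNMT3A2, a short isoform of DNMT3A, and the second DNMT3B1, an isoform of DNMT3B. The third line also expressed DNMT3B1 and additionally lacked SETD2, the enzyme that trimethylates lysine 36 of histone H3 in transcribed gene bodies. The labels listed 2 sequencing runs per line and no separate cultures, so each line was 1 library, no p-value between lines was computed, and binomial intervals cover counting error only. Values of the DNMT3A2 and DNMT3B1 lines came as 1 set per line and were taken as both runs pooled. The 2 files of the SETD2 knockout held identical values and were counted as 1 sample, and it is open whether they hold 1 run or both runs pooled.

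The CpG sites carried 200364080 reads in the DNMT3A2 line, 188661576 in the DNMT3B1 line and 200947834 in the SETD2 knockout line. Mean coverage was 11.4 reads over 17597542 sites with reads for DNMT3A2 and 10.8 over 17397449 for DNMT3B1. The SETD2 knockout values listed 9293499 sites, each with at least 10 reads, at a mean coverage of 21.6. Levels across all 3 lines were compared on 7065841 sites with at least 5 reads in each line, which had a mean coverage between 12.7 reads in DNMT3B1 and 18.9 in the SETD2 knockout. Positions are those of genome build mm9. Tiles are described by position and CpG density, because gene models of that build were not used here.

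The first comparison asked how much methylation each line carried across the genome. The level was 7.28% of CpG reads in the DNMT3A2 line (exact 95% binomial interval 7.27% to 7.28%) and 2.75% in the DNMT3B1 line (2.75% to 2.76%). The level in the DNMT3A2 line was thus 2.64 times that in the DNMT3B1 line. In the absence of SETD2 the DNMT3B1 level was 5.87% (5.86% to 5.87%). This was 2.13 times the level of the DNMT3B1 line, with a standard error of 0.0078 from leaving out 1 chromosome at a time, and 0.806 times that of the DNMT3A2 line. Single autosomes ranged from 6.60% to 7.71% for DNMT3A2, from 2.59% to 2.93% for DNMT3B1 and from 5.51% to 6.24% for the SETD2 knockout, so that the ranges of the lines did not overlap. No methylated read was seen at 63.3% of sites with DNMT3A2, 84.2% with DNMT3B1 and 63.9% in the SETD2 knockout, shares that also depend on depth, which was highest in the knockout. Sites methylated in at least 50% of their reads made up 2.01%, 0.592% and 1.06% of sites, in the same order. The levels include any cytosines that escaped bisulfite conversion. The amount of each reintroduced enzyme was not measured here, so the levels describe lines and not the activity of an enzyme.

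At the sites compared, of matched CpG density (10 to 19 CpGs per kb), the X chromosome was less methylated than the autosomes in all 3 lines. DNMT3A2 methylated 7.14% of X reads (6.91% to 7.38%) against 9.17% on the autosomes, a ratio of 0.779. DNMT3B1 methylated 2.91% of X reads (2.76% to 3.07%) against 3.31%, a ratio of 0.879. In the SETD2 knockout the X level was 6.54% (6.36% to 6.72%) against 6.93%, a ratio of 0.943. The X values rested on 5235 sites, and the differences between the 3 ratios were not tested. At this CpG density X coverage was 0.315 and 0.310 times that of the median autosome in the DNMT3A2 and DNMT3B1 lines. The knockout listed 9.98% of X sites against 50.7% on its median autosome. The coverage minimum thus kept a smaller share of X sites, and whether that selection changed the ratios was not tested.

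Local CpG density, counted as CpG sites in the 1 kb around a site, set levels apart more than chromosome did. CpG-dense DNA, the class that holds CpG islands, was almost free of methylation in each line. At 60 or more CpGs per kb, DNMT3A2 methylated 0.211% of reads (0.207% to 0.214%), DNMT3B1 0.153% (0.150% to 0.156%) and the SETD2 knockout 0.463% (0.459% to 0.467%). At 10 to 19 CpGs per kb the levels were 9.17%, 3.31% and 6.93%. The level at 10 to 19 CpGs per kb was thus 43.5 times that of the densest DNA with DNMT3A2, 21.6 times with DNMT3B1 and 15.0 times in the SETD2 knockout. At 1 to 4 CpGs per kb the levels were 5.62%, 2.83% and 6.53%, lower than at 10 to 19 CpGs per kb in all 3 lines, by 1.63, 1.17 and 1.06 times.

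**Figure D1:**
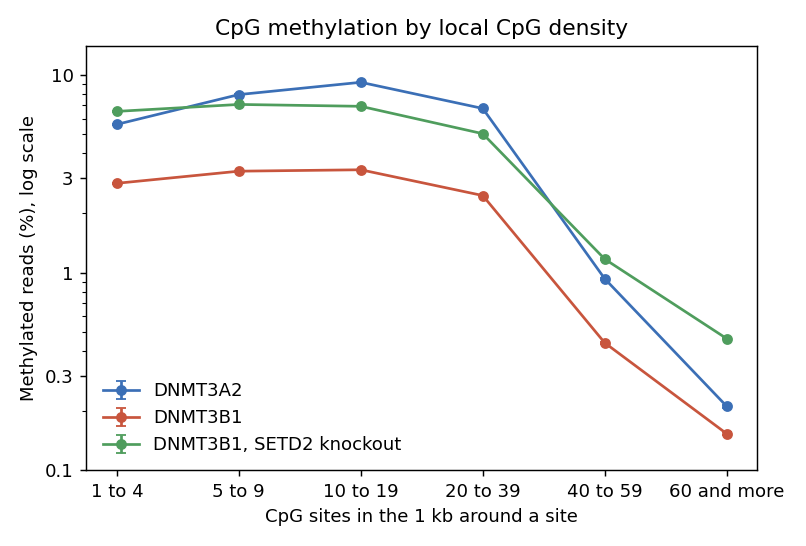
Methylated reads in percent (vertical axis, log scale) against the number of CpG sites in the 1 kb around a site (horizontal axis, 6 bins) for the DNMT3A2, DNMT3B1 and DNMT3B1 SETD2 knockout lines. Points are levels pooled over sites, and the bars, mostly smaller than the points, are exact 95% binomial intervals; the DNMT3A2 level went from 9.17% at 10 to 19 CpGs per kb to 0.211% at 60 and more.

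Relative to the genome-wide ratio, DNMT3B1 methylation exceeded DNMT3A2 methylation at both ends of the density range. The relative log2 ratio of DNMT3B1 over DNMT3A2 was 0.41 ± 0.01 (standard error over chromosomes) at 1 to 4 CpGs per kb, -0.07 ± 0.004 at 10 to 19, 0.33 ± 0.03 at 40 to 59 and 0.94 ± 0.05 at 60 and more. The ratio of the SETD2 knockout over DNMT3B1 had the same shape, with 0.12 ± 0.01 at 1 to 4 CpGs per kb, -0.03 ± 0.003 at 10 to 19, 0.32 ± 0.06 at 40 to 59 and 0.51 ± 0.04 at 60 and more. At levels as low as those of the densest bin, unconverted cytosines weigh more than elsewhere.

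The next comparison asked where DNMT3B1 and DNMT3A2 differed beyond their genome-wide ratio. Of 160890 tiles of 10 kb, 7573 were relatively higher with DNMT3B1, by at least 2-fold with a 95% interval that excluded no difference, and 6610 were relatively lower. The relatively higher tiles were poorer in CpGs, with a median of 8.69 CpGs per kb against 12.2 in the lower tiles. Their median level was 3.97% with DNMT3A2 and 5.44% with DNMT3B1, and 6.44% in the SETD2 knockout. In the relatively lower tiles the median level was 10.8% with DNMT3A2, 1.23% with DNMT3B1 and 6.64% in the SETD2 knockout. Over all tiles compared, the medians were 7.53%, 2.79% and 6.44%, so the knockout level in both sets of tiles, which were selected on the other lines' ratio, was close to that of all tiles. In absolute terms the DNMT3B1 level exceeded the DNMT3A2 level in 11594 tiles (7.21%).

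The 5 tiles with the highest relative ratio had a mean of 21.6 to 60.4 CpGs per kb around their sites and between 0 and 3 methylated reads with DNMT3A2. Tiles without a methylated read in a line were set to the floor of 3 reads and so ranked as less extreme than tiles with 1 read, here and in the sets of tiles that follow. The tile at chromosome 1 from 120200001 to 120210000 had 0.0880% methylation with DNMT3A2 (1 of 1136 reads), 1.84% with DNMT3B1 (17 of 924) and 2.33% in the SETD2 knockout, a relative log2 ratio of 5.77 (95% interval 2.00 to 9.54). On chromosome 4 from 111080001 to 111090000 the levels were 0.166% (1 of 601), 2.37% (16 of 674) and 4.29%, a relative log2 ratio of 5.22 (1.33 to 9.12). On chromosome 13 from 12950001 to 12960000 DNMT3A2 left 0 of 686 reads methylated, a level of 0.437% at the floor of 3 reads, with an exact 95% upper limit of 0.536%. DNMT3B1 methylated 3.84% there (23 of 599 reads) and the SETD2 knockout 10.5%, and the relative log2 ratio with DNMT3A2 set to that floor was 4.52 (2.64 to 6.40). The tile on chromosome 14 from 84840001 to 84850000 had 0.0506% with DNMT3A2 (1 of 1978 reads, exact 95% interval 0.00128% to 0.281%) and 0.428% with DNMT3B1 (11 of 2572, 0.214% to 0.764%), a relative log2 ratio of 4.47. That on chromosome 1 from 175290001 to 175300000 (3 of 1066 reads and 19 of 886) had one of 4.32 (2.15 to 6.48). The intervals of these last tiles, on chromosomes 14 and 1, each included 0 under 1 other setting, and at a coverage minimum of 1 read the ratios of the tiles at 120200001 on chromosome 1 and on chromosome 4 were 3.45 ± 3.33 and 2.78 ± 2.39 (95% intervals).

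The 5 tiles with the lowest relative ratio were well methylated by DNMT3A2 and held 1 methylated read each with DNMT3B1, a count favoured by the floor. On chromosome 19 from 56890001 to 56900000 DNMT3A2 methylated 6.54% (85 of 1300 reads) and DNMT3B1 0.0678% (1 of 1476), a relative log2 ratio of -5.21 (-8.38 to -2.04). On chromosome 11 from 4430001 to 4440000 the levels were 12.5% (85 of 681) and 0.165% (1 of 606), a ratio of -4.85 (-7.72 to -1.99). The tiles on chromosome 1 from 166290001 to 166300000, chromosome 9 from 70510001 to 70520000 and chromosome 13 from 36730001 to 36740000 had levels of 12.3%, 10.6% and 12.5% with DNMT3A2 and ratios of -4.78 (-7.79 to -1.78), -4.76 (-7.33 to -2.19) and -4.64 (-7.74 to -1.54). At a coverage minimum of 1 read the ratio of this tile on chromosome 1 was -1.61, with a 95% interval that only narrowly excluded 0, and with the background subtracted the 5 ratios were between -3.53 and -2.99. Subtraction also raised the DNMT3B1 levels of these tiles to the floor of 3 reads, so the floor as well as the background moved these ratios. The SETD2 knockout line, which expressed the same DNMT3B1 isoform, had 3.91%, 4.95%, 5.33%, 6.11% and 7.51% methylation in these 5 tiles, in the order given.

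**Figure D2:**
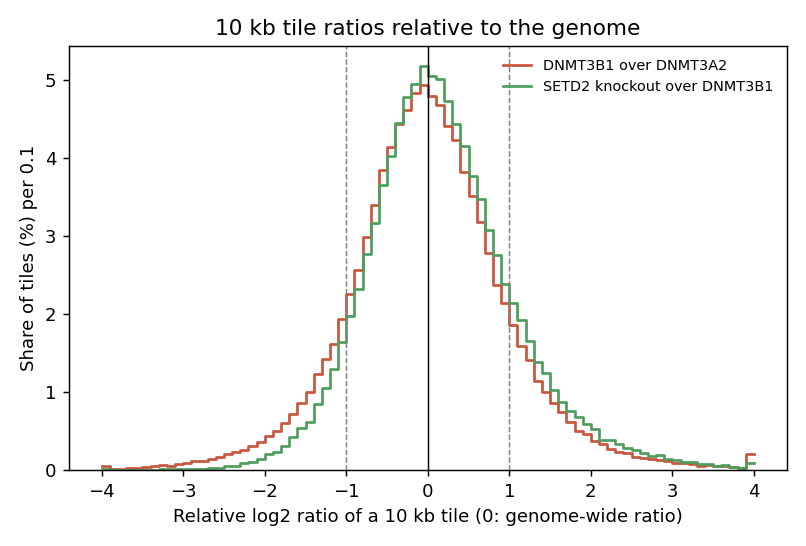
Share of 10 kb tiles in percent (vertical axis) by relative log2 ratio in steps of 0.1 (horizontal axis, 0 being the genome-wide ratio; the end steps at -4 and 4 hold all tiles beyond them) for DNMT3B1 over DNMT3A2 and for the SETD2 knockout over DNMT3B1. Dashed lines mark 2-fold; both distributions peak near 0, and the first extends further below -1.

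In simulated tiles without any change, 3537 were called higher and 3752 lower with the variation between clusters of neighbouring CpGs estimated from the data, and 6937 and 5892 with a relative variance of 1, so single called tiles are not established differences. At a coverage minimum of 1 read the split was 14595 higher against 7376 lower, at a minimum of 10 reads 2630 against 3753, in 5 kb tiles 9299 against 11684, and in 50 kb tiles 3090 against 367, so which direction held more tiles turned with the coverage minimum and the tile size.

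The third comparison asked where methylation differed between the SETD2 knockout line and the DNMT3B1 line. The level was higher in the SETD2 knockout than in the DNMT3B1 line in 113004 of 120431 tiles (93.8%). Relative to the genome-wide ratio, 5268 tiles were at least 2-fold higher in the knockout with a 95% interval that excluded no difference, and 3574 were lower by the same rule. In the relatively higher tiles the median level was 0.885% in the DNMT3B1 line and 8.05% in the knockout, with 7.54% in the DNMT3A2 line. In the relatively lower tiles it was 6.51% in the DNMT3B1 line, 4.97% in the knockout and 8.51% with DNMT3A2. Over all tiles the medians were 2.80%, 6.56% and 7.94%, in the same order. Simulated tiles without change gave 3131 higher and 2592 lower with the estimated variation, and 4720 and 5305 with a relative variance of 1, above the observed count of lower tiles. By difference of percentile ranks, 3143 tiles were higher, and in 50 kb tiles 1203 were higher and 471 lower.

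In the 5 tiles with the highest relative ratio, 1 methylated read each was seen in the DNMT3B1 line, a count again favoured by the floor. On chromosome 11 from 5600001 to 5610000 the level was 0.0358% in the DNMT3B1 line (1 of 2796 reads) and 1.93% in the knockout (83 of 4309), a relative log2 ratio of 4.66 (1.45 to 7.86). On chromosome 2 from 17950001 to 17960000 it was 0.0855% (1 of 1170) and 4.39% (102 of 2322), a ratio of 4.59 (2.13 to 7.05). The tiles on chromosome 3 from 122330001 to 122340000, chromosome 15 from 83570001 to 83580000 and chromosome 4 from 136910001 to 136920000 reached 5.63%, 6.11% and 3.80% in the knockout. Their ratios were 4.57 (2.08 to 7.06), 4.51 (2.15 to 6.87) and 4.51 (1.19 to 7.83). DNMT3A2 methylated 1.30%, 1.62%, 5.26%, 5.11% and 1.62% in these 5 tiles. The interval of the tile on chromosome 2 included 0 at a coverage minimum of 10 reads, and with the background subtracted the 5 ratios were between 2.71 and 2.89. Here too subtraction raised the DNMT3B1 levels to the floor of 3 reads, so the shift is not that of the background alone.

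The lowest relative ratio belonged to a CpG-dense tile on chromosome 10 from 12810001 to 12820000. It was methylated at 27.6% with DNMT3A2 (296 of 1073 reads) and at 16.9% with DNMT3B1 (195 of 1157 reads, 14.7% to 19.1%), but in the SETD2 knockout in 14 of 1166 reads (exact 95% interval 0.658% to 2.01%). The relative log2 ratio was -4.91 (-6.70 to -3.11). The other 4 tiles had between 5 and 11 methylated reads in the DNMT3B1 line and 1 or 2 in the knockout. They lay on chromosome 19 from 12870001 to 12880000, with a ratio of -4.35 (-7.36 to -1.34), chromosome 1 from 162140001 to 162150000, with -4.30 (-7.99 to -0.62), chromosome 8 from 44380001 to 44390000, with -4.21 (-7.60 to -0.82), and chromosome 7 from 28790001 to 28800000, with -3.79 (-6.89 to -0.69). The intervals of the tiles on chromosomes 19, 1 and 7 included 0 under at least 1 other setting.

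The last comparison asked whether regions preferred by DNMT3B1 over DNMT3A2 kept that preference without SETD2. Because both ratios hold the DNMT3B1 reads, 96374 tiles were ranked by the DNMT3B1 over DNMT3A2 ratio in odd-numbered clusters of CpGs, and all ratios were then measured in even-numbered clusters, which share no sites with them, although reads can span a border between clusters. From the lowest to the highest decile of tiles, the median relative log2 ratio of DNMT3B1 over DNMT3A2 went from -0.31 ± 0.02 to 0.14 ± 0.04, a range of 0.45 ± 0.03. The ratio of the SETD2 knockout over DNMT3B1 went the other way, from 0.31 ± 0.02 to 0.05 ± 0.03, a difference of -0.25 ± 0.03. Its ratio over DNMT3A2 was 0.01 ± 0.01 in the lowest decile, -0.01 ± 0.01 in the seventh and 0.16 ± 0.03 in the highest, so that the highest deciles carried its span of 0.15 ± 0.02. The ranking and each measured ratio share a line, so a regional deviation of the single DNMT3B1 or DNMT3A2 line alone would also give a span. With the same clusters used for ranking and measuring, the difference of the knockout over DNMT3B1 grew to -2.33, a value that includes the counting error shared by both ratios.

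**Figure D3:**
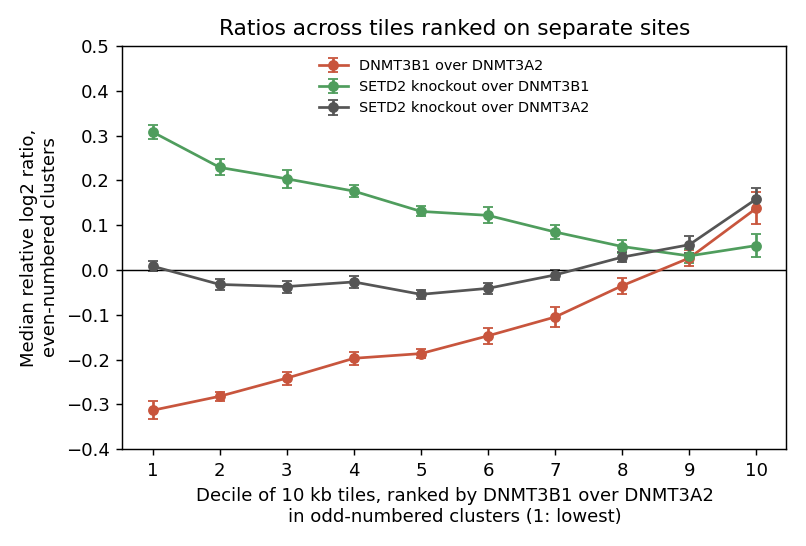
Median relative log2 ratio in even-numbered clusters (vertical axis) for 10 kb tiles in deciles ranked by DNMT3B1 over DNMT3A2 in odd-numbered clusters (horizontal axis), for the 3 pairs of lines. Bars are standard errors from leaving out 1 chromosome at a time; DNMT3B1 over DNMT3A2 goes from -0.31 to 0.14, and the SETD2 knockout over DNMT3A2 spans 0.15.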

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

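Of the tests below, that of repeats alone was chosen only after the result was seen, and the windows were picked by coverage after the data had been examined.

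The coverage maximum kept the most deeply covered CpG sites out of the comparisons at the main settings. In 5 windows of 20 kb, at least 40 sites had 500 or more reads in each of the 3 lines. On chromosome 2 from 98500001 to 98520000, 59 such sites held 22344029 reads in the DNMT3A2 line, and the pooled level was 8.05% with DNMT3A2, 2.06% with DNMT3B1 and 5.37% in the SETD2 knockout. On chromosome 9 the levels of 57 sites from 3000001 to 3020000 were 10.3%, 3.25% and 7.41%, and those of 77 sites from 3020001 to 3040000 were 10.2%, 2.44% and 6.54%. On chromosome 11 from 3080001 to 3100000, 43 sites had pooled levels of 5.51%, 1.47% and 5.20%. On chromosome 17 from 39980001 to 40000000, 476 sites had 0.0971%, 0.162% and 0.585%, the only window of the 5 in which DNMT3B1 lay above DNMT3A2. Pooled levels follow the sites with the most reads, and the medians over sites, in the same order of lines, were 7.54%, 2.99% and 7.45% on chromosome 2, 4.92%, 1.01% and 5.35% on chromosome 11, and 0.0278%, 0.112% and 0.473% on chromosome 17, so that DNMT3A2 and the knockout were closer on chromosome 2 and changed places on chromosome 11.

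In the window on chromosome 2 the 2 lines with DNMT3B1 shared a site profile that the DNMT3A2 line did not have: the rank correlation of site levels was 0.95 between DNMT3B1 and the SETD2 knockout, 0.274 between DNMT3A2 and DNMT3B1, and 0.256 between DNMT3A2 and the knockout. At sites within 10 kb tiles of the rest of the genome, the correlation of DNMT3B1 with the knockout exceeded that of DNMT3A2 with the knockout by 0.074 ± 0.002 (0.178 against 0.104). The order was thus not limited to the highly covered windows. A feature of repeats alone cannot be decided from this, because repeats were not annotated and the rest of the genome was not cleared of them. A site preference that differs between DNMT3A2 and DNMT3B1 may account for the pattern: in 4 of the 4 other windows the pair with DNMT3B1 had the highest rank correlation, from 0.198 on chromosome 17 to 0.908 on chromosome 9, although in both windows of chromosome 9 DNMT3A2 also correlated with the 2 DNMT3B1 lines, at 0.503 to 0.646. Sites are not independent replicates, and neither are the 2 windows of chromosome 9, which adjoin. Levels on chromosome 17 were low (0.0971% with DNMT3A2, 0.162% with DNMT3B1 and 0.585% in the knockout), so unconverted cytosines weigh more there. Each line is 1 library, and collapsed repeat copies, mapping and a shared origin of the 2 DNMT3B1 lines were not tested and stay open. The sequence around the sites was not analysed here, so this stays a hypothesis.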

How the results depend on the processing

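The alternatives for single-line sites, for sites of 10 to 19 CpGs per kb, for 2 kb clusters and for all tile correlations were chosen after seeing the data. The order DNMT3A2, SETD2 knockout, DNMT3B1 of genome-wide levels held under every alternative run, although at these read numbers small shifts left the binomial intervals. In that order the levels were 7.43%, 5.76% and 2.61% without a coverage maximum, 7.30%, 5.99% and 2.78% as the mean of the sites' own levels, 7.20%, 5.69% and 2.72% at a minimum of 10 reads, and 7.29%, 5.95% and 2.81% on each line's own sites. At a minimum of 1 read they were 5.95% for the knockout and 2.76% for DNMT3B1. In the densest CpG bin DNMT3A2 was at 0.220% at a minimum of 10 reads and DNMT3B1 at 0.160% without a coverage maximum. The knockout was at 0.471%, 0.458%, 0.470% and 0.475% at a minimum of 1 read, of 10 reads, as the mean of sites and without a maximum.

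For DNMT3B1 over DNMT3A2, 14595 tiles were higher at a minimum of 1 read, 2630 higher and 3753 lower at 10 reads, 3090 higher and 367 lower in 50 kb tiles, and 9299 higher and 11684 lower in 5 kb tiles. For the knockout over DNMT3B1, 1203 were higher and 471 lower in 50 kb tiles, 5413 lower in 5 kb tiles, and 3143 higher by percentile ranks, which require 50 points of difference. The cause of the changed counts and splits was not tested. Of the values of named tiles under the alternatives, 88 kept their direction with an interval excluding 0 (the largest move from -4.78 to -1.61) and 8 with one including 0. Some named tiles of DNMT3B1 over DNMT3A2 no longer qualified at a minimum of 10 reads and gave no value there. They were those from 166290001 on chromosome 1, 111080001 on chromosome 4, 70510001 on chromosome 9 and 36730001 on chromosome 13. The opposite trends of the ratios across tiles held under all alternatives run, with the knockout over DNMT3B1 from -0.17 at a minimum of 1 read to -0.34 at 10 reads, apart from the -2.33 of shared clusters. The lead of the DNMT3A2-knockout over the DNMT3B1-knockout correlation of tile levels, 0.078 ± 0.010 in 10 kb tiles, turned to -0.023 ± 0.021 in 50 kb and -0.12 ± 0.02 in 200 kb tiles. Among sites of 10 to 19 CpGs per kb it was 0.138 ± 0.043 in 50 kb and -0.059 ± 0.051 in 200 kb tiles, and the cause stays open.

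No paired analysis was possible because the replicate numbers are names given in accession order to sequencing runs whose reads were taken as pooled or were identical in the values used. For the same reason leaving out single runs was not run, nor was a correction by spike-in or mitochondrial reads or any gene-based alternative. With a median of 544 to 810 reads per tile and line at these levels, depth limits named tiles to wide intervals, and lowered tiles were recovered less often than raised ones in simulated data.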

Other observations

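Tests of unconverted cytosines, site listing, other cells, CpG density, a deviating line and the loss of SETD2, as well as the choice of CpG-dense stretches, were made only after the result was seen; the test with fewer methylated reads was set before.

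A few CpG-dense stretches stood out against an almost unmethylated class. Of 9079 stretches with at least 60 CpGs per kb, 10 sites and 200 reads in each line, counting sites of any coverage up to the maximum, 12 were methylated at 5% or more with DNMT3A2, 4 with DNMT3B1 and 9 in the SETD2 knockout, and the median stretch had 0.0979%, 0.0670% and 0.344%. On chromosome 10 from 12810307 to 12811197, the stretch inside the tile with the lowest knockout ratio, 35.3% of reads were methylated with DNMT3A2 (exact 95% interval 32.8% to 37.9%), 19.7% with DNMT3B1 (17.4% to 22.1%) and 0.240% in the SETD2 knockout (2 of 835 reads, 0.0290% to 0.863%). On chromosome 2 from 152512706 to 152513025 the levels were 13.2%, 4.47% and 0 of 598 reads in the knockout. The opposite was seen on chromosome 5 from 35917323 to 35917748, with 1 of 450 reads, 0 of 408 reads and 11.9% (41 of 345 reads, 8.66% to 15.8%), and on chromosome 17 from 34767717 to 34768080, with 0.430%, 0 of 361 reads and 6.62%. With 1 line per condition these values have no replicate check.

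Mean coverage per site differed between chromosomes in the same way in the DNMT3A2 and DNMT3B1 lines. Chromosome 11 had 1.63 and 1.62 times the coverage of the median autosome, chromosome 6 had 1.43 and 1.42 times, chromosome 8 had 1.28 and 1.27 times, and the X chromosome 0.315 and 0.310 times. The other 16 autosomes lay between 0.899 and 1.03 times. In the SETD2 knockout the share of sites of that CpG density that were listed was also highest on chromosome 11, at 74.4%, and was 9.98% on the X chromosome.

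The level of the SETD2 knockout line lay above that of the DNMT3B1 line by 3.11 percentage points genome-wide. Unconverted cytosines would raise all sites alike, and a rise of 0.31 percentage points in the densest CpG bin argues against them as the whole difference. The listing of sites with at least 10 reads cannot be judged from the DNMT3B1 level, because the 2 lines were compared at the same sites. That level was 0.951 times as high at listed sites as at sites not listed (2.76% and 2.90%). Selection through the knockout's own reads was not tested. DNA of other cells such as feeder cells could add to the difference and cannot be told apart from a change in the line, since the methylation of such cells is not known here: the median rise was 2.12 points in the lowest and 3.51 points in the highest decile of tiles by DNMT3B1 level, a ratio of 1.66. A different amount of the reintroduced enzyme and an effect of SETD2 loss stay open as well, and neither was tested. The knockout runs were also labelled with other run types, and their values came separately with a minimum of 10 reads. A difference in sequencing or processing therefore cannot be told apart from the genotype.

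In 10 kb tiles the SETD2 knockout line was closer to DNMT3A2 than to the line with its own enzyme, with correlations of 0.908 ± 0.009 and 0.830 ± 0.008 after removal of counting error, an order also seen in 50 kb tiles at 10 to 19 CpGs per kb (difference 0.138 ± 0.043) but not over all sites in 50 kb tiles nor in 200 kb tiles. CpG density is argued against as the whole cause, because the difference was 0.166 ± 0.013 among sites of 10 to 19 CpGs per kb. With DNMT3A2 thinned to the DNMT3B1 level the difference was 0.0715 ± 0.012. That value cannot decide whether fewer methylated reads in DNMT3B1 matter, because thinning adds only counting error, which the correlations already remove. A deviation of the single DNMT3B1 line or library cannot be told apart from an effect of SETD2, since in 10 kb tiles DNMT3B1 had the lower correlation with both other lines (0.783 with DNMT3A2), whereas in 200 kb tiles over all sites, where this order was absent, DNMT3A2 correlated more with DNMT3B1 (0.845 ± 0.024) than with the knockout (0.734 ± 0.016). The hypothesis that loss of SETD2 removes the regional preference of DNMT3B1 stays open too: the knockout kept 33.3% of the DNMT3B1 range over DNMT3A2 (50.8% at a coverage minimum of 1 read), but both ranges share the DNMT3A2 line, so this share decides nothing. The separate sequencing runs and processing of the knockout stay open for this order as well. A second line of each genotype, sequenced and processed alike, would be needed to tell these explanations apart.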
